A study of Mus musculus with 6 samples.

How the data were processed

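Polyadenylated RNA was profiled in 3 control and 3 pressure-exposed samples of primary mouse liver sinusoidal endothelial cells. Per the labels' protocols, hepatocytes were removed by low-speed centrifugation, dead cells and erythrocytes by a density gradient, and endothelial cells were picked with CD146 beads. Libraries came from a stranded mRNA kit and were read on an Illumina NovaSeq as single reads of 101 bases. Per the submitters' processing notes, TopHat2 2.2.1, Cufflinks 2.2.1 and the genome build mm10 were used; which step each served, the counting tool, its strand setting and the annotation are not given in the sources used here. The authors deposited expected counts (estimated counts that need not be whole) per gene symbol, with fractions in 18.22% to 21.67% of the detected genes of a library. Such fractions can arise when reads that map to several places are split, which the files do not show, so genes with near-identical copies are uncertain. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart either. The files list 24421 symbols, none more than once and none with the prefix of mitochondrially encoded genes, and 6374 had no read in any library.

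Depth ranged from 12922959 counts (pressure replicate 3) to 18655749 (control replicate 1). The samples were grouped by the submitters' titles. No 2 libraries agreed within sampling noise: the chi-square statistic per degree of freedom over genes was at least 2.961 for every pair within a group. Counts were rounded to whole numbers. Genes were kept by filterByExpr (minimum count 10, minimum total count 15, groups of 3), which left 12892 genes with 99.94% of counts. Library sizes were scaled by TMM factors (control 1.074 to 1.083, pressure 0.9094 to 0.9457). Pressure was compared with control by edgeR 4.0.16 quasi-likelihood F-tests (R 4.3.3), two-sided, without covariates, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are TMM-scaled CPM computed from the rounded counts.

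Before the data were examined, 50 gene lists (pathways, endothelial subtypes and markers of other cell types), a panel of 12 genes, the tests and the alternatives were fixed. Lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided) and adjusted over the 44 lists tested. The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library totals only, other low-count filters, the sample number as a block, offsets for GC content and length, stricter thresholds, leaving out the 50 most abundant genes, and leaving out each sample in turn. Leaving out mitochondrially encoded genes was planned too, but the files list no such symbol. For the list test, they also included an estimated correlation and fry. GC content and exonic length came from the GENCODE M21 annotation of GRCm38 and were found for 99.03% of tested genes.

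Genes were named by a fixed rule. It took, among genes past the threshold with a mean of at least 5 CPM, no overlap between the groups and no clone or predicted symbol, the 12 largest rises and the 12 largest falls. It added, for each list, up to 4 members past the threshold with the smallest p, or the 2 most abundant measured members if none passed, and the panel. Some genes that the rule selected are not reported here. A further 11 gene families, in the closing section, were chosen after the data were seen. Data simulated from the observed means and library sizes for the same comparison and 12892 genes tested the gene test: 71.64% of genes changed 1.5-fold, 95.52% of those changed 2-fold and 98.48% of those changed 4-fold were recovered, and 3.8% of calls were false. In the simulation the changed list was called and 0 of 20 unchanged lists were. It changed 67, 67 and 66 genes at these folds and drew the counts of each gene independently. The simulated spread followed the trend with expression level, without a spread particular to a gene or an outlying library. These rates therefore do not cover a change of most genes, correlated genes, genes of unusual spread or a library that stands apart. Intervals for shares are exact binomial intervals at 95% (scipy 1.17.1) and cover counting error only.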

Results

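The series measured mRNA levels in primary mouse liver sinusoidal endothelial cells (LSECs), the fenestrated endothelium that lines the hepatic sinusoids and clears waste molecules from portal blood. The cells were selected from wild-genotype livers with magnetic beads against CD146, an endothelial surface protein, plated overnight on collagen I and serum-starved for 6 h. The pressure group then received periodic hydrostatic pressure that cycled between 101 and 135 kPa (absolute) at 0.01 Hz for 8 h, and the other group served as control. No duration or handling over those 8 h is labelled for the controls. A difference in culture time or handling therefore cannot be told apart from pressure. Each group held 3 samples, all under a single batch label, and the comparison asks which transcripts differ after pressure loading. Library totals lay between 12922959 and 18655749 deposited counts, and 12892 of the 24421 listed genes had enough counts for testing. The labels do not say whether the 3 samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Unless stated otherwise, a log2 fold change is pressure over control with its standard error (edgeR), and a level is the mean ± SD of CPM (counts scaled to library size with TMM factors) with n = 3 per group. Levels are given as control to pressure.

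Across single genes, the largest changes under pressure included rises of a chemokine, a metallothionein and an adhesion molecule. Cxcl2, a neutrophil-attracting chemokine, went from 7.66 ± 0.174 to 207 ± 30.2 CPM (log2 fold change 4.75 ± 0.13). The metallothionein Mt2 rose by 4.33 ± 0.21 and reached 507 ± 167 CPM, and Sele, the leukocyte adhesion molecule E-selectin, rose from 2.44 ± 0.299 to 40.95 ± 2.37 CPM. Others of the 12 largest rises were Lancl3, Phlda1, Gcm1, Mum1l1, Nfil3, Igfbp3, Bcat1 and Arid5a, whose log2 changes lay between 3.26 (Arid5a) and 3.76 (Lancl3). Among them, Bcat1 encodes the cytosolic branched-chain aminotransferase, and Nfil3 a basic leucine zipper repressor. The 12 largest falls were Spice1, Fat3, C5ar2, Vamp5, Ushbp1, Clec9a, Slc16a9, Pcdh12, Tmem194, Trim34a, Tmem204 and Mtcp1, with log2 changes from -4.32 (Spice1) to -3.23 (Mtcp1). Ushbp1 was the most abundant of these in controls and went from 140.5 ± 6.99 to 10.3 ± 2.58 CPM. Pcdh12, an endothelial protocadherin, went from 18.8 ± 0.972 to 1.74 ± 0.373 CPM, and C5ar2, a receptor for complement C5a, from 18.4 ± 1.92 to 1.23 ± 0.381 CPM. In GRCm38 (the build named mm10, with the GENCODE M21 annotation), Cxcl2 spans chromosome 5 from 90903871 to 90905938, Mt2 chromosome 8 from 94172664 to 94173568, Sele chromosome 1 from 164048234 to 164057677 and Ushbp1 chromosome 8 from 71384272 to 71395802. All 4 are annotated as protein-coding, and these spans cover exons, introns and untranslated regions.

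In total, 8871 of 12892 genes (68.81%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4347 higher and 4524 lower under pressure. An absolute log2 fold change of at least 1 was reached by 3006 of them, 1243 higher and 1763 lower, and 590 changed at least 4-fold, 280 higher and 310 lower. For 3023 called genes the change was below 1.5-fold. The 3 pressure values all lay above or all below the 3 control values for 9271 genes (71.9%), where chance gives 10%. The first principal component of log CPM held 86.81% of the variance and separated the groups, with controls from -52.7 to -50.2 and pressure libraries from 43.2 to 59.2. The direction split depended on the scaling: with library totals and no composition factor, 3129 of 9016 called genes (34.7%) were higher and 5887 lower. The median log2 change of all genes moved by -0.213 with that setting and by -0.114 with upper-quartile scaling. Changes near 0 therefore have no fixed sign. In all, 7521 genes were called with the same direction under all 4 scalings, 3129 higher and 4392 lower. Pressure replicate 3 stood apart from the other pressure libraries, with correlations of log CPM to them of 0.9868 and 0.9894 where the third pair gave 0.9941, and leaving it out gave 9746 called genes.

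**Figure D1:**
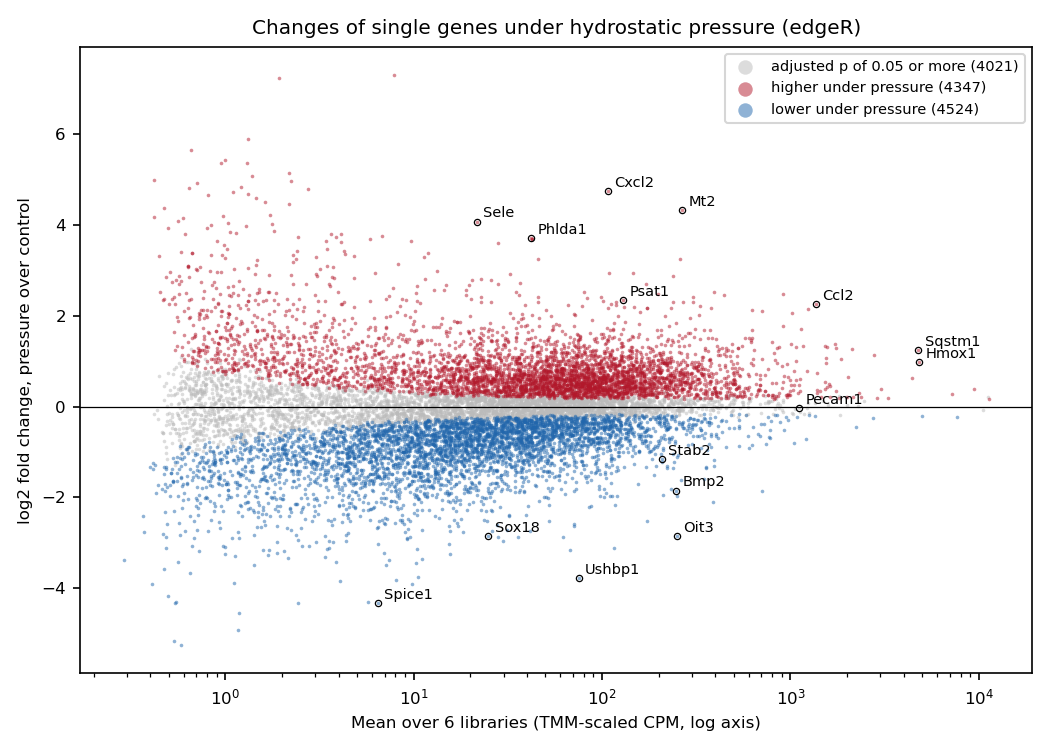
Log2 fold change (pressure over control) of each of the 12892 tested genes against its mean TMM-scaled CPM over the 6 libraries on a log axis, with points in red for genes called higher (4347), blue for genes called lower (4524) and grey for the rest. Cxcl2, Mt2 and Sele lie at the upper edge, Ushbp1 and Spice1 at the lower edge, and Pecam1 near 0 (-0.042 ± 0.059).

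The 50 gene lists fixed before the data were examined gave 44 with at least 5 measured members, and 10 of these passed an adjusted p of 0.05 in camera, a competitive test of whether members rank higher or lower than other genes. Of those, 9 were higher and 1 was lower under pressure. Lists overlap to differing degrees. Members also found in another list were 13 of 25 angiogenesis, 12 of 20 LSEC identity and 10 of 17 continuous-capillary genes, but 1 of 28 immediate-early genes. The 10 calls are therefore not all separate findings. All 10 used the preset correlation between genes of 0.01; with a correlation estimated for each list none passed (adjusted p from 0.264 to 0.639, and 4 lists at an unadjusted p under 0.05), whereas fry, which only asks whether members move on balance one way, called 27. For each list whose number of risen or fallen members changed by at least 3 with library totals only, those counts are given too (a rule chosen after the data were seen). Member counts adjusted over the list alone equalled those over all genes except in 9 lists, where both are given. The medians of the 10 lists kept their sign under all 4 scalings, while those of 12 other lists, with medians between -0.221 and 0.206, did not (antigen presentation, apoptosis regulators, cell junction, cholesterol synthesis, extracellular matrix, haemostasis, mechanosensors and ion channels, oxidative phosphorylation, periportal endothelial, ribosomal protein, stellate cell and smooth muscle and unfolded protein response).

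**Figure D2:**
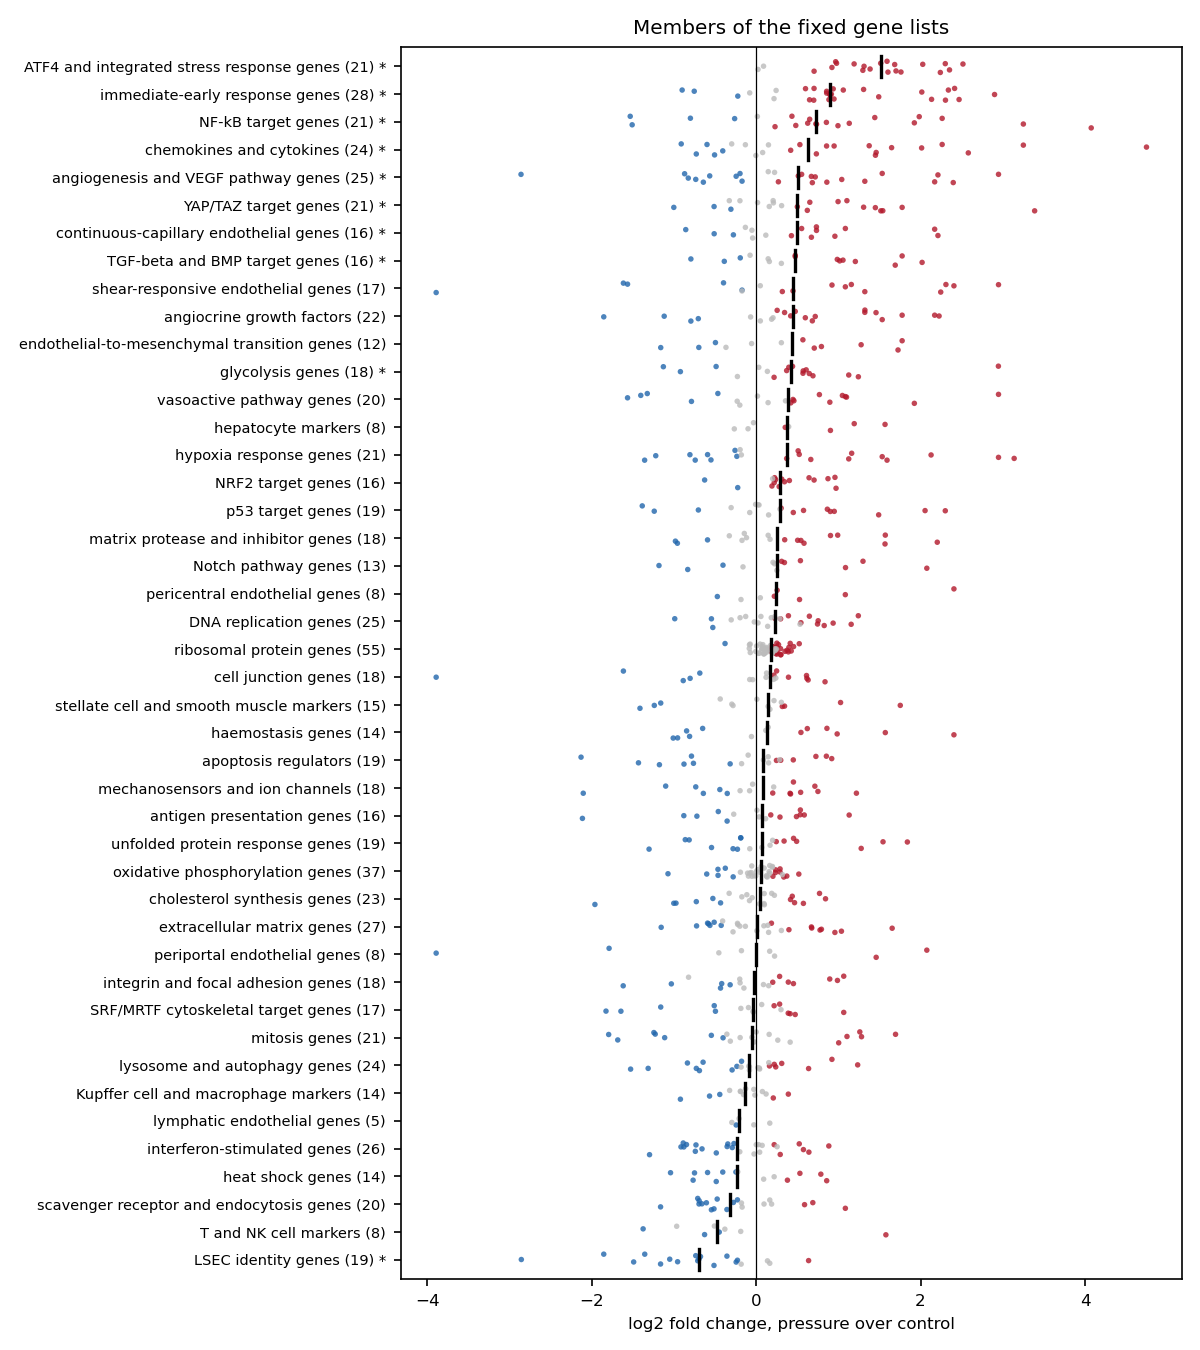
Log2 fold change (pressure over control, x axis) of every measured member of the 44 tested gene lists (y axis, number of members in brackets), red for members that rose, blue for members that fell, grey for the rest, and a black bar at each list's median. Asterisks mark the 10 lists past an adjusted p of 0.05 in camera, with medians from 1.52 for the integrated stress response list at the top to -0.69 for the LSEC identity list at the bottom.

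Integrated stress response and immediate-early genes rose under pressure, while other stress lists moved both ways. In the list of ATF4 and integrated stress response genes, which act when translation initiation is restrained by phosphorylated eIF2α, 19 of 21 members rose and 0 fell, with a median log2 change of 1.52 (camera adjusted p = 2.30e-17; adjusted p = 0.264 with an estimated correlation). Psat1 and Phgdh, enzymes of serine synthesis, rose by 2.35 ± 0.077 and 2.03 ± 0.093. Ppp1r15a, the regulatory subunit of the eIF2α phosphatase, went from 117 ± 9.30 to 669.5 ± 70.1 CPM, and Slc3a2, the heavy chain of amino acid exchangers, from 533 ± 30.3 to 1734 ± 118 CPM. Among immediate-early genes, transcription factors and regulators induced within minutes to hours of a stimulus, 22 of 28 rose and 3 fell (camera adjusted p = 4.29e-06; adjusted p = 0.349 with an estimated correlation). Klf6 went from 279 ± 12.2 to 1543 ± 274 CPM, Myc rose by 2.02 ± 0.075, Fosl1 by 2.41 ± 0.15, and Fos, at a low level, from 2.99 ± 0.0533 to 15.1 ± 1.39 CPM. The unfolded protein response list split, with 7 of 19 higher and 8 lower (camera adjusted p = 0.658). The chaperone Hspa5 (BiP) rose from 1013 ± 37.6 to 2458 ± 46.04 CPM, Herpud1 rose by 1.84 ± 0.11 and Dnajb9 by 1.54 ± 0.090, while Sdf2l1, another chaperone of the endoplasmic reticulum, fell (-1.30 ± 0.11). Heat shock genes also split, 4 higher and 7 lower of 14 (camera adjusted p = 0.933). Hsp90aa1 changed by 0.79 ± 0.11 and Chordc1 by -0.59 ± 0.084.

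NRF2 targets, the antioxidant gene set, had 13 of 16 members higher and 2 lower (camera adjusted p = 0.0558; 0.0318 without the low-count filter, and 0.0373, 0.0497 and 0.0496 without pressure replicate 1, 2 or 3; adjusted p = 0.349 with an estimated correlation). With library totals only, 6 members were higher and 2 lower. Hmox1, heme oxygenase 1, went from 3259 ± 162 to 6394 ± 434 CPM, and Gclc, the catalytic subunit of glutathione synthesis, rose by 0.96 ± 0.092. Of 19 p53 targets 9 rose and 3 fell (7 higher and 6 lower with library totals only; camera adjusted p = 0.172, and 0.0272 without pressure replicate 3; adjusted p = 0.727 with an estimated correlation). Mdm2, the p53 ubiquitin ligase, rose by 1.49 ± 0.14, and the sestrins went apart, Sesn2 (also in the integrated stress response list) at 2.30 ± 0.12 and Sesn1 at -1.38 ± 0.12. Apoptosis regulators moved both ways, 6 higher and 7 lower of 19 (3 higher and 9 lower with library totals only; camera adjusted p = 0.843), with a positive median (0.089) but a negative mean (-0.19) and test direction: the survival gene Mcl1 rose by 0.85 ± 0.076, and Casp8, Bmf and Bad, which promote cell death, fell (-1.43, -2.13 and -1.18).

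Chemokine, cytokine and NF-kB target transcripts rose as groups. Of 24 chemokines and cytokines, 14 rose and 5 fell (11 higher and 5 lower with library totals only; camera adjusted p = 5.67e-05; adjusted p = 0.349 with an estimated correlation). Cxcl1, a neutrophil attractant, went from 49.6 ± 4.60 to 472 ± 70.1 CPM, Ccl2, a monocyte attractant, from 471 ± 44.5 to 2259.9 ± 454 CPM, and Il1a from 56.8 ± 0.576 to 156 ± 8.53 CPM, and Cxcl10 rose by 1.65 ± 0.096. Of 21 NF-kB targets, 16 rose and 4 fell (camera adjusted p = 5.24e-05; adjusted p = 0.349 with an estimated correlation). Nfkbiz, a nuclear IκB protein, changed by 1.98 ± 0.11. The lists share members such as Cxcl1. In contrast, interferon-stimulated genes had 6 members higher and 13 lower of 26 (camera adjusted p = 0.507). Oasl2 and Ifih1 fell (-1.30 and -0.85) and Cmpk2 rose (0.88). Antigen presentation genes had 7 higher and 5 lower of 16 (camera adjusted p = 0.933, with median 0.077, mean -0.055 and a positive test direction). Psmb9, an immunoproteasome subunit, changed by -2.11 ± 0.15 and the costimulatory Cd86 by 1.13 ± 0.091. Macrophage transcripts were abundant in both groups. Cd5l stood at 2559.9 ± 101 CPM in controls and 1885 ± 102 CPM under pressure and Csf1r at 159 ± 10.7 CPM in controls and 209 ± 17.97 CPM under pressure.

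**Figure D3:**
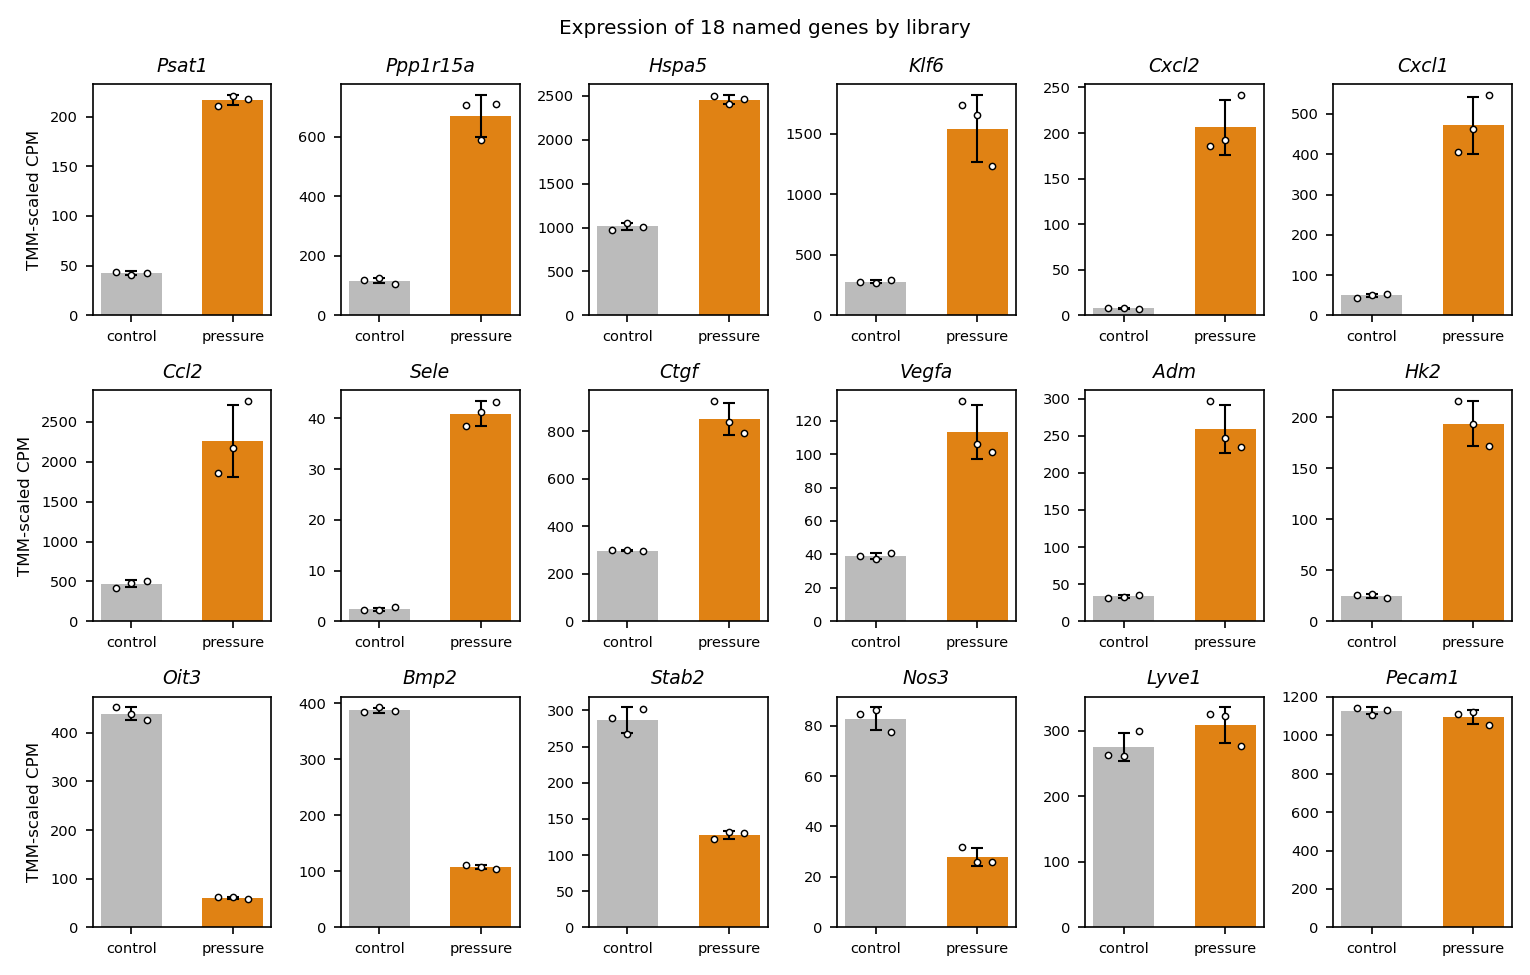
TMM-scaled CPM (y axis, linear from 0) of 18 named genes in control and pressure libraries (x axis), with bars for means, error bars for SD (n = 3) and open circles for single libraries. For Psat1 through Hk2 all pressure libraries lie above all controls, for Oit3, Bmp2, Stab2 and Nos3 all lie below, and Lyve1 and Pecam1 overlap.

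Most genes that define LSECs fell. In the LSEC identity list 15 of 19 members fell and 1 rose, with a median log2 change of -0.69 (camera adjusted p = 5.24e-05; adjusted p = 0.349 with an estimated correlation). Oit3, a liver-specific zona pellucida domain protein, went from 438 ± 13.1 to 60.5 ± 2.61 CPM, Bmp2, an LSEC signal that induces hepcidin in hepatocytes, from 387 ± 4.54 to 107 ± 3.63 CPM, and the hyaluronan scavenger receptor Stab2 from 286 ± 17.5 to 128 ± 5.54 CPM. Plxnc1 fell by 1.35, and Ctsl, encoding cathepsin L, was the member that rose (0.64 ± 0.054). Dnase1l3 (-0.18 ± 0.088) and Gata4 (0.14 ± 0.071) passed in neither direction. Lyve1, another hyaluronan receptor of these cells, stood at 275 ± 21.3 CPM in controls and 309 ± 27.4 CPM under pressure (0.17 ± 0.088, adjusted p = 0.114, but 0.00269 without pressure replicate 3), and the general endothelial gene Pecam1 at 1127 ± 17.5 CPM in controls and 1095 ± 36.8 CPM under pressure (-0.042 ± 0.059, adjusted p = 0.544). Pecam1 passed as lower with upper-quartile scaling and with library totals only (-0.16 and -0.26), settings that lower the median of all genes. Among scavenger receptor and endocytosis genes, of which 9 of 20 are also in an endothelial list, 12 of 20 fell and 3 rose (camera adjusted p = 0.291). Stab1 went from 1498 ± 38.97 to 916 ± 90.6 CPM and the mannose receptor Mrc1 from 966 ± 42.02 to 597 ± 54.99 CPM, while Cav1, the coat protein of caveolae, rose by 1.09 ± 0.11.

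Genes of continuous, non-fenestrated capillaries rose in 9 and fell in 3 of 16 members (7 higher and 6 lower with library totals only; camera adjusted p = 0.0403; adjusted p = 0.349 with an estimated correlation). The basement membrane collagen gene Col4a1 went from 1051 ± 38.1 to 2041 ± 167 CPM, the transcription factor gene Sox17 from 27.8 ± 1.48 to 129 ± 23.3 CPM and Apln, a peptide of endothelial tip cells, from 84.7 ± 7.84 to 382 ± 28.02 CPM, whereas Ly6a fell (-0.86 ± 0.075). This call was lost without control replicate 2 (adjusted p = 0.0557), with library totals only (0.0553) and with a minimum mean of 5 CPM (0.0626). Cd34 rose by 0.43 ± 0.11, and its call was lost with library totals only (adjusted p = 0.128). Zonal endothelial lists did not pass: 5 of 8 pericentral genes rose and 1 fell (camera adjusted p = 0.273), and 2 of 8 periportal genes rose and 2 fell (camera adjusted p = 0.933, with a negative median of -0.0067 and a positive test direction). Of the pericentral genes, Thbd (thrombomodulin) went from 96.6 ± 11.3 to 512 ± 119 CPM and Kit fell (-0.47 ± 0.079). Of the periportal genes, Efnb2 rose by 2.08 ± 0.13 and Ntn4 fell (-1.79 ± 0.090). The lymphatic list had 5 measured members, of which 1 fell over all genes and none passed when adjusted over the list alone (camera adjusted p = 0.933). Of 13 Notch pathway genes 6 rose and 3 fell (3 higher and 4 lower with library totals only; camera adjusted p = 0.549). Rbpj, the pathway's nuclear effector, changed by 1.09 ± 0.11 and the endothelial receptor Notch4 by -1.18 ± 0.11.

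Angiogenesis genes moved both ways, with more rises than falls. Of 25 angiogenesis and VEGF pathway genes, 14 rose and 9 fell (camera adjusted p = 0.0197; adjusted p = 0.578 with an estimated correlation). Pgf (placental growth factor) went from 26.4 ± 1.73 to 139 ± 13.8 CPM, Vegfa from 39.1 ± 2.02 to 113 ± 16.1 CPM and Adm (adrenomedullin) from 33.6 ± 1.77 to 259 ± 32.6 CPM, and the VEGF receptor gene Kdr went from 209.9 ± 10.1 to 126 ± 2.89 CPM and Sox18 from 43.7 ± 3.73 to 6.12 ± 1.69 CPM. Angiocrine growth factors, secreted by endothelium to act on parenchyma, had 14 of 22 members higher and 4 lower (10 higher and 4 lower with library totals only; camera adjusted p = 0.0648; 0.0271 with the sample number as a block, 0.0489 without the low-count filter, 0.042 without control replicate 3 and 0.0497 without pressure replicate 2; adjusted p = 0.578 with an estimated correlation). Angpt2 changed by 1.32 ± 0.081. Shear-responsive genes had 10 of 17 higher and 5 lower (10 and 6 adjusted over the list alone; camera adjusted p = 0.0562). That list passed with the block (0.0271), upper-quartile scaling (0.0492), no low-count filter (0.0248) and without pressure replicate 1, 2 or 3 (0.0215, 0.0459 and 0.00392), and had an adjusted p = 0.578 with an estimated correlation. Its flow-induced members moved apart: Klf2 rose from 8.83 ± 1.57 to 20.04 ± 6.48 CPM and Nos3, the endothelial nitric oxide synthase, went from 82.6 ± 4.51 to 27.9 ± 3.45 CPM. In the vasoactive list, 10 of 20 rose and 5 fell (camera adjusted p = 0.507). Ptgs1 (cyclooxygenase 1) changed by 1.09 ± 0.093 and Ddah2 by -1.32 ± 0.11. Edn1 (endothelin 1) rose by 0.45 ± 0.10, a call lost with library totals only (adjusted p = 0.072). Haemostasis genes had 6 higher and 5 lower of 14 (camera adjusted p = 0.744). Pros1 (protein S) changed by -0.81 ± 0.059 and Plat (tissue plasminogen activator) by 1.57 ± 0.15. Vwf stood at 13.1 ± 1.28 CPM in controls and 14.1 ± 3.64 CPM under pressure (adjusted p = 0.558, and 0.0271 without pressure replicate 3).

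For genes tied to mechanical load, YAP/TAZ targets rose in 11 and fell in 3 of 21 members (camera adjusted p = 0.00779; adjusted p = 0.578 with an estimated correlation). Ctgf went from 298 ± 2.75 to 852 ± 67.95 CPM, Cyr61 from 34.6 ± 2.47 to 101 ± 5.20 CPM and Igfbp3 from 2.08 ± 0.199 to 21.8 ± 1.54 CPM. Targets of SRF and its actin-sensing cofactors split, 6 higher and 5 lower of 17 (2 higher and 9 lower with library totals only; camera adjusted p = 0.940). Zyx (zyxin) changed by 1.07 ± 0.075, Actg1 by 0.48 ± 0.076, Cnn2 (calponin 2) by -1.83 ± 0.12 and Tpm1 by -0.51 ± 0.072. Mechanosensors and ion channels had 8 higher and 6 lower of 18 (8 and 7 adjusted over the list alone; camera adjusted p = 0.933, with median 0.080, mean -0.042 and a negative test direction). Piezo1, a stretch-activated cation channel, went from 176 ± 7.63 to 235 ± 20.03 CPM, and Trpv2 and Kcnj2 fell (-1.10 and -2.10). Integrin and focal adhesion genes had 7 higher and 5 lower of 18 (4 higher and 8 lower with library totals only; camera adjusted p = 0.940, with a negative median and a positive test direction). Itgb3 changed by -1.62 ± 0.078 and Bcar1 by 0.90 ± 0.10. Cell junction genes likewise had 7 higher and 5 lower of 18 (4 higher and 6 lower with library totals only; camera adjusted p = 0.936, median 0.17, mean -0.21, test direction positive), among them Ctnnd1 (p120 catenin) at -0.68 ± 0.067 and the connexin gene Gja4 at -1.61 ± 0.18.

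Of 16 TGF-beta and BMP targets, 9 rose and 3 fell (camera adjusted p = 0.0294; adjusted p = 0.349 with an estimated correlation), a call lost without pressure replicate 3 (adjusted p = 0.101) and with a minimum mean of 5 CPM (0.0626). Id1 and Id2, BMP-induced inhibitors of differentiation, rose by 1.69 ± 0.12 and 1.02 ± 0.076, and Bambi and Smad7, which restrain TGF-beta signalling, by 2.02 ± 0.17 and 1.06 ± 0.096. In the endothelial-to-mesenchymal transition list 6 of 12 rose and 3 fell (camera adjusted p = 0.435). The intermediate filament gene Vim went from 1236 ± 87.2 to 2997 ± 145 CPM, and the transcription factors moved apart, Snai2 at 1.73 ± 0.17 and Zeb1 at -0.70 ± 0.076. Extracellular matrix genes had 9 higher and 7 lower of 27 (8 and 7 adjusted over the list alone; 7 higher and 12 lower with library totals only; camera adjusted p = 0.922). Thbs1 (thrombospondin 1) changed by 1.65 ± 0.15 and Loxl3, a collagen crosslinking enzyme, by -1.15 ± 0.093. Matrix protease and inhibitor genes had 9 higher and 3 lower of 18 (6 higher and 7 lower with library totals only and with upper-quartile factors; camera adjusted p = 0.336), and Plaur, the urokinase receptor, went from 129 ± 10.2 to 382 ± 28.5 CPM.

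In metabolism, glycolysis genes rose in 12 and fell in 3 of 18 members (12 and 4 adjusted over the list alone; camera adjusted p = 0.0197; adjusted p = 0.639 with an estimated correlation). Hk2 (hexokinase 2) went from 25.1 ± 1.95 to 194 ± 21.8 CPM, the glucose transporter gene Slc2a1 from 48.9 ± 2.24 to 107 ± 6.22 CPM and Pkm (pyruvate kinase) from 1572 ± 76.7 to 2460.4 ± 191 CPM. Hypoxia response genes had 11 higher and 8 lower of 21 (camera adjusted p = 0.0625; 0.0332 without the low-count filter, and 0.0237, 0.0497 and 0.0415 without pressure replicate 1, 2 or 3; adjusted p = 0.349 with an estimated correlation). Ero1l, an oxidase of the endoplasmic reticulum, changed by 1.16 ± 0.079 and the secreted glycoprotein gene Stc2 by 3.14 ± 0.22. Oxidative phosphorylation genes had 8 higher and 6 lower of 37 (7 and 6 adjusted over the list alone; camera adjusted p = 0.922), and 2 higher and 12 lower with library totals only. Cytochrome c (Cycs) changed by 0.52 ± 0.068. Cholesterol synthesis genes had 6 higher and 6 lower of 23 (5 higher and 9 lower with library totals only; camera adjusted p = 0.933, median 0.042, mean -0.091, test direction positive). Fdft1 (squalene synthase) changed by 0.77 ± 0.073 and Nsdhl by -0.97 ± 0.11.

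Of 55 ribosomal protein genes 24 rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 0.172), while with library totals only 3 rose and 3 fell and the median went from 0.18 to -0.028. Many of these genes have pseudogene copies. Lysosome and autophagy genes had 7 higher and 9 lower of 24 (3 higher and 14 lower with library totals only; camera adjusted p = 0.922). The autophagy receptor gene Sqstm1 (p62) went from 2847 ± 141 to 6704 ± 508 CPM, and the sialidase gene Neu1 from 125 ± 7.33 to 43.6 ± 4.62 CPM. DNA replication genes had 11 higher and 3 lower of 25 (8 higher and 3 lower with library totals only; camera adjusted p = 0.295). The replication clamp gene Pcna changed by 0.75 ± 0.071 and Mcm7 by 0.94 ± 0.083. Of 25 mitosis genes 2 reached a mean of 5 CPM. The list had 5 higher and 7 lower of 21 (5 and 6 adjusted over the list alone; camera adjusted p = 0.933), and Mki67 stood at 2.47 ± 0.717 CPM in controls and 5.83 ± 1.36 CPM under pressure.

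Markers of other liver cells that the bead selection could carry over did not pass in camera in any tested list, and macrophage transcripts were plentiful. None of the 14 Kupffer cell and macrophage markers is in another list, and all had a mean of at least 5 CPM. Of these 2 rose and 3 fell (camera adjusted p = 0.839), and with library totals only none rose and 8 fell. Cd5l went from 2559.9 ± 101 to 1885 ± 102 CPM and Vsig4 from 85.8 ± 3.80 to 57.9 ± 6.79 CPM, while Csf1r rose by 0.39 ± 0.087, a call lost with library totals only (adjusted p = 0.0739). Stellate cell and smooth muscle markers, of which 4 of 17 are in another list, had 4 higher and 3 lower of 15 (3 and 3 adjusted over the list alone; 2 higher and 6 lower with library totals only; camera adjusted p = 0.933, median 0.15, mean -0.035, test direction positive). Des (desmin) and Acta2 changed by -1.24 and -1.16, and Tcf21 and Dcn by 1.75 and 0.35. The call of Dcn was lost with library totals only (adjusted p = 0.124). Hepatocyte markers were scarce, with 8 of 23 measured, 4 higher and 0 lower (camera adjusted p = 0.658), and Alb (albumin), which dominates hepatocyte mRNA, stood at 6.40 ± 1.55 CPM in controls and 12.1 ± 1.54 CPM under pressure. Of 8 measured T and NK cell markers 1 rose and 3 fell (camera adjusted p = 0.922). Gzmb stood at 0.536 ± 0.263 CPM in controls and 1.59 ± 0.304 CPM under pressure, while Klrb1c, Cd4 and Il7r fell (-1.37, -0.63 and -0.45). Klrb1c had few counts (0.712 to 0.259 CPM). The calls of Klrb1c and Cd4 were lost with DESeq2 (adjusted p = 0.0759 and 0.0707), and that of Cd4 also without control replicate 1 (0.0557). The call of Il7r was lost without control replicate 2, control replicate 3 or pressure replicate 1 (0.0865, 0.075 and 0.0849). The other 6 lists had too few measured members for the list test. Of 4 cholangiocyte markers 3 rose, among them Spp1 from 3.37 ± 0.256 to 6.95 ± 0.639 CPM, and of 4 dendritic cell markers Clec9a fell (-3.77) and Xcr1 rose (1.99). Of 3 monocyte and neutrophil markers Csf3r fell (-1.08), the only measured B cell marker, Cd22, fell (-0.95), and of 3 red cell and platelet markers Gp1ba rose (1.52). Neither of 2 mesothelial markers passed (Gpm6a at -0.20 ± 0.19 and Lrrn4 at -0.23 ± 0.39). Of the 190 genes that the naming rule selected, 60 had fractional counts in at least 1 library, among the genes above Cxcl1, Cxcl2, Ccl2, Il1a, Hk2, Pkm, Stab2 and Nos3. Fgf2, on the fixed panel, had too few counts for testing.

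**Figure D4:**
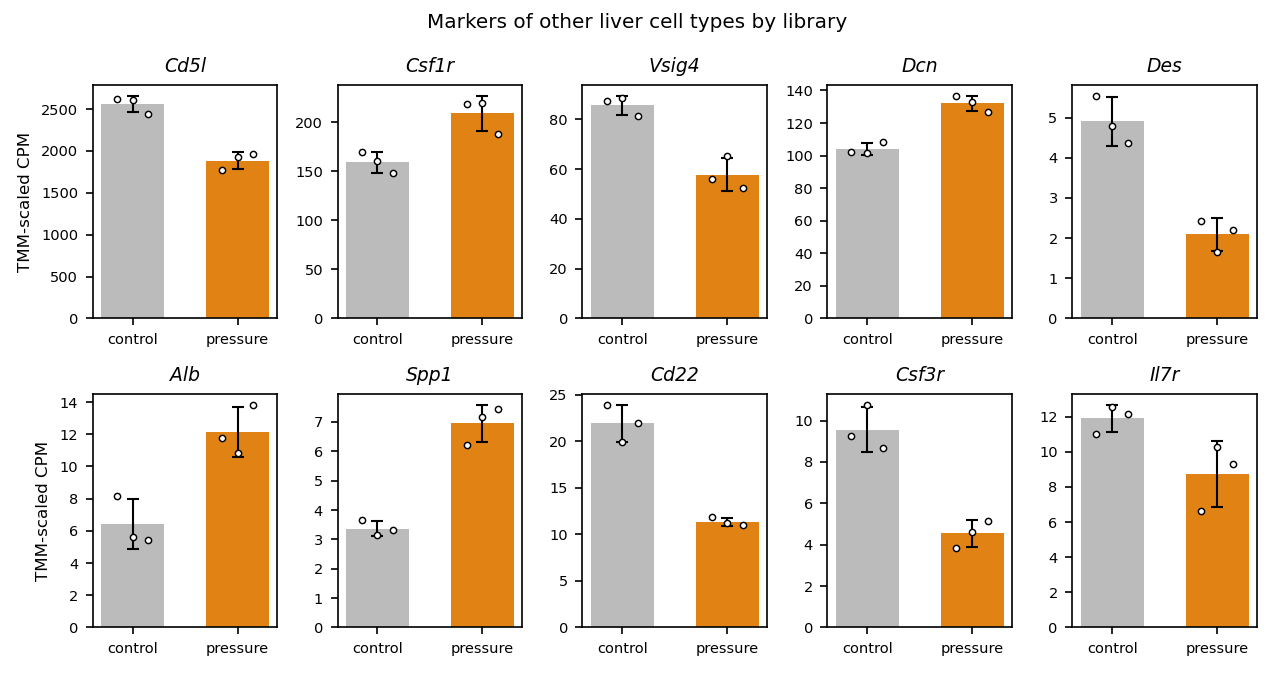
TMM-scaled CPM (y axis, linear from 0, each gene on its own scale) of 10 marker genes of other liver cell types in control and pressure libraries (x axis), with bars for means, error bars for SD (n = 3) and open circles for single libraries. The macrophage marker Cd5l lies at 2559.9 ± 101 CPM in controls and 1885 ± 102 CPM under pressure, while the hepatocyte marker Alb, the stellate marker Des and the cholangiocyte marker Spp1 lie below 15 CPM in all libraries.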

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

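All alternatives below were chosen before the data were examined. The count of 8871 called genes stayed within 1.5 times under each of them except a log2 fold change of at least 1 as a second threshold, which by construction gave 3006 (1243 higher, 1763 lower). Leaving out 1 sample gave 7981 to 9746 called genes (3887 to 4780 higher, 4094 to 4966 lower), the most without pressure replicate 3, and 9 to 14 called lists in place of 10. With an estimated correlation 0 lists passed, and with fry, which tests another hypothesis, 27. The estimated correlation of the TGF-beta and BMP target list (-0.0295) lay below the preset 0.01. Its unadjusted camera p still rose from 0.006 to 0.042, so a higher correlation does not account for the loss of that call. The other called lists had estimated correlations of 0.0184 (continuous-capillary genes) to 0.24 (glycolysis genes), and the cause was not tested. No clear pairing by sample number was seen: the deviations of same-numbered libraries correlated at 0.129, -0.23 and -0.134, and not every sample correlated best with its own number. Pairing cannot be excluded with 3 samples per group. With the number as a replicate block, 8384 genes and 12 lists were called.

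List directions that turned did so only for lists past the threshold in neither setting, 17 times in 612 comparisons, and the cause was not tested. Adjusted p of camera or fry follow. Integrin and focal adhesion genes turned down with fry (0.924), upper-quartile factors (0.981), library totals only (0.983) and no low-count filter (0.983). Mitosis genes turned up with upper-quartile factors (0.981) and library totals only (0.924). Cell junction and cholesterol synthesis genes turned down with library totals only (0.995 each). SRF/MRTF targets turned up with a minimum mean of 5 CPM (0.884). Leaving out 1 sample in turn turned the direction of 7 uncalled lists at least once, with adjusted p over the 6 fits of 0.814 to 0.979 (antigen presentation genes), 0.891 to 0.99 (cholesterol synthesis genes), 0.931 to 0.99 (integrin and focal adhesion genes), 0.814 to 0.979 (mechanosensors and ion channels), 0.748 to 0.979 (oxidative phosphorylation genes), 0.629 to 0.979 (periportal endothelial genes) and 0.931 to 0.979 (stellate cell and smooth muscle markers).

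Of the 185 called among 190 named genes, 118 kept call and direction under every alternative. The log2 threshold of 1 removed 64 of the calls. No called gene turned. Genes past the threshold in neither setting turned 8 times. Lyve1 (-0.0485) and Vwf (-0.099) turned with library totals only, and Pecam1 with GC and length offsets (0.00702) and with these and the replicate block (0.00697). Leaving out 1 sample gave log2 changes of -0.33 to 0.00541 (Gpm6a), -0.473 to 0.147 (Lrrn4) and -0.0508 to 0.295 (Vwf). Library totals only moved the median of all genes by -0.213, more than the main log2 changes of Lyve1 (0.17) and Vwf (0.12). That shift accounts for their turns under this setting. The cause of the other turns was not tested. Depth limits the genes with few counts: of simulated 1.5-fold changes, 2 of 15 were recovered at a mean under 5 CPM and 46 of 52 above (Fisher's exact test, two-sided p = 9.01e-08, a split chosen after the data were seen).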

Other observations

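The gene families in the next 2 paragraphs were chosen after the data were seen, as were all their tests (camera with the preset correlation, adjusted over the 11 families). Their adjusted p therefore describe these families and do not control false calls. Of 20 cytosolic tRNA synthetase genes 14 rose and 3 fell (adjusted p = 0.000785; adjusted p = 0.108 with an estimated correlation), led by Gars, which went from 315 ± 6.99 to 896 ± 33.8 CPM, and Tars (1.35 ± 0.075), while Qars fell (-0.78 ± 0.081). Of 54 translation initiation factor genes 40 rose and 2 fell (adjusted p = 1.0e-05; adjusted p = 0.108 with an estimated correlation), with Eif3c at 1.42 ± 0.064 and Eif4e, the cap-binding protein, at 1.12 ± 0.080. Of 38 proteasome subunit genes 28 rose and 4 fell (adjusted p = 0.000238; adjusted p = 0.36 with an estimated correlation); Psmc4 rose by 0.95 ± 0.079, and the immunoproteasome subunit Psmb9 fell (-2.11 ± 0.15). Of 42 snoRNA and snoRNA host genes 23 rose and 2 fell (adjusted p = 0.00108; adjusted p = 0.234 with an estimated correlation), with Snhg1 at 1.79 ± 0.095. These medians kept a positive sign under all 4 scalings. With library totals only, 29 initiation factor genes rose and 7 fell, and 25 proteasome genes rose and 6 fell. Of the snoRNA and host genes, 18 rose and 3 fell with that setting. Some snoRNA genes lay near the floor, with Snord16a at 0.427 to 2.21 CPM and Snora21 at 0.121 to 1.21 CPM. Snord16a, Snord69 and Snora7a lay behind Rpl4, Gnl3 and Rpl32, which rose in the main test. In polyadenylated RNA, counts of such snoRNA genes may come from transcripts of these neighbours. Of single genes, also chosen after their values were seen, Mt1 rose from 136 ± 16.3 to 748 ± 234 CPM, the zinc exporter gene Slc30a1 from 123 ± 4.69 to 277 ± 19.04 CPM, and the zinc importer gene Slc39a10 fell from 89.6 ± 5.55 to 15.4 ± 3.08 CPM.

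Of 16 circadian clock genes 12 rose and 3 fell (adjusted p = 0.00185; adjusted p = 0.108 with an estimated correlation): the activator Arntl (Bmal1) rose from 14.5 ± 1.29 to 77.1 ± 0.437 CPM, and Dbp and Per3 fell (-1.72 and -1.81). Of 7 GIMAP GTPase genes 6 fell and none rose (adjusted p = 0.000113; adjusted p = 0.108 with an estimated correlation), with Gimap8 going from 149 ± 9.73 to 44.3 ± 3.69 CPM. Of 22 intraflagellar transport and Bardet-Biedl genes, which build primary cilia, 14 fell and 1 rose (adjusted p = 0.00108; adjusted p = 0.108 with an estimated correlation), with Bbs7 at -3.14 ± 0.15 and Ift172 at -1.88 ± 0.14. Of 10 Toll-like receptor genes 7 fell and 1, Tlr2, rose (adjusted p = 0.00514; adjusted p = 0.186 with an estimated correlation); Tlr1 went from 19.2 ± 1.47 to 2.89 ± 0.472 CPM. Fanconi anaemia genes (1 higher, 6 lower of 9; adjusted p = 0.212), numbered Zfp genes (112 higher, 107 lower of 304; adjusted p = 0.564) and pan-endothelial genes (5 higher, 7 lower of 18; adjusted p = 0.875) did not pass. The medians of the GIMAP, intraflagellar transport and Toll-like receptor families were negative and that of clock genes positive under all 4 scalings; with library totals only, 8 clock genes rose and 3 fell, 18 intraflagellar transport and Bardet-Biedl genes fell and 1 rose, and 82 numbered Zfp genes rose and 141 fell.

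Next, 3 patterns were weighed; the tests of run-on transcription as the whole source and of shared reads were set before their results were seen, and all other tests of this part after. The first is the breadth of the change, 8871 of 12892 genes. If a bias from GC content and gene length had produced this breadth, offsets for both would lower the count of called genes. With these offsets 9243 genes were called, against 8797 of the same 12767 genes without. The choice of scaling does not account for the breadth as a whole either, since 7521 genes were called in 1 direction under all 4 scalings. The 10 splits of the 6 libraries are too few for a share under 0.05; edgeR called 8871 genes in the real split, the 1 split with as many, and none in the others (at most 238 at an unadjusted p under 0.05). A response to pressure, which the design names, stays open and was not tested. So does a difference in culture time or handling between the groups, which the labels do not exclude.

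The second pattern is the fall of the LSEC identity genes. A smaller share of endothelial cells would lower general endothelial genes as well. The median of 18 pan-endothelial genes lay 0.648 above that of the LSEC list (bootstrap over genes, 95% interval 0.162 to 1.11). That interval treats genes as independent and leaves out the spread between samples. The pan-endothelial genes moved both ways, from Sox18 (-2.86) to S1pr1 (1.78). Their median was -0.046 in the main test and -0.26 with library totals only (4 higher, 9 lower). The bootstrap asked only whether both sets fell by the same amount. A smaller endothelial share as a part of the fall therefore stays open. The list median lay between -0.909 and -0.672 over the 4 scalings, and its members ranged from Oit3 (-2.86) to Ctsl (0.64), with Lyve1 at 0.17. A smaller share of sinusoidal cells among the endothelial cells stays open, since members that other cells also express would fall less than the rest. Lower expression per cell stays open as well, and no test here decides between these.

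The third pattern is 159 genes with a control mean under 0.5 CPM that rose to at least 1 CPM (132 fell the other way), among them Tnfrsf19 and Ccno (named after their values were seen). Transcription running on for up to 10 kb from a risen neighbour upstream on the same strand does not account for most of them. Longer run-on, or run-on from a neighbour that did not rise, was not tested. Of the 159 genes, 14.5% (23, exact binomial 95% interval 9.4 to 20.9%) lay that close to a risen neighbour at 5 CPM or more. That share exceeded the 6.01% among the other risen genes (247 of 4110; Fisher's exact test, two-sided p = 0.000155), so for those 23 genes, Apol8 behind Myh9 for example, run-on or host-gene transcription may contribute. Reads shared between repeats are no general source if fractional counts mark them, as 38.4% had fractional counts (30.8 to 46.4%), against 40.5% of the other tested genes under 5 CPM; for the 61 genes with such counts they stay open. Induction by pressure is a candidate explanation for the rest and was not tested.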
